A study of Rattus norvegicus with 30 samples.

How the data were processed

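Gene expression was measured in microglia, the resident macrophages of the brain, isolated from male rats after transient occlusion of the middle cerebral artery. The occlusion lasted 75 min under 1.2% isoflurane, per the labels' protocols. The rats were 3 or 12 months old, and microglia were taken 3 or 14 days after the stroke from the ipsilateral (injured) and the contralateral (opposite) hemisphere, or from sham controls. The labels name the strain in conflicting ways: the sample characteristics give Wistar Kyoto and the protocols give spontaneously hypertensive rats. How the microglia were isolated, and from which hemisphere the sham samples came, is not given in the sources used here. Total RNA had integrity numbers above 7.0. From 50 ng of RNA, cDNA was amplified with a NuGEN Pico whole-transcriptome kit, and 5 µg was labelled and hybridised to Affymetrix Rat Gene 1.0 ST arrays, per the labels' protocols.

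The deposited values were log2 expression values of 29214 probe sets on 30 arrays, made by the authors with Affymetrix Expression Console and RMA (background correction, quantile normalization and summary over the probes of a probe set), per the submitters' processing notes, which give no versions. The values ran from 2.18 to 13.68 and the array medians from 5.06 to 5.24. They were used without further scaling. The standard deviation of the values over an array was 1.79 to 1.93 on the stroke arrays of 3-month rats and 1.94 to 2.05 on the other arrays, so the deposited arrays did not share 1 distribution. Whether the arrays were summarised in 1 run is not given in the sources used here. No pair of arrays held identical values, and arrays of 1 group correlated at 0.9865 to 0.9953 (Pearson's r across probe sets, median 0.9929). The number of arrays limits the precision.

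Probe sets were named through the platform's annotation, with symbols updated against a table of RefSeq genes of the assembly GRCr8, used for names only. Of the probe sets, 15310 had 1 gene symbol, 323 had several and 13581 were not listed, and those with several or none were left out of the main test. Symbols were updated through the gene identifier for 15279 probe sets and through an accession for 6, and kept as given for 25; 2 symbols changed. This named 14506 genes. A probe set was kept where its value lay above the 30th percentile of its array (4.07 to 4.35) on at least 3 arrays, which 22343 probe sets did. Each gene was tested once, on the probe set with the highest mean over all arrays, which left 11675 genes. The sources used here give no detection calls, so a gene of a group whose 3 arrays all lay at or below their 30th percentile was treated as having a bound there: the text gives the brighter group's mean minus that group's mean of the higher of value and percentile, as "at least", beside the fitted value. This step was added after the data were examined. Different probe sets of a gene were averaged in an alternative.

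The 30 samples formed 10 groups of 3. Differences between group means were tested with limma (lmFit and eBayes) in 1 model of the group means over all 30 arrays, with 20 residual and 8.8 prior degrees of freedom. Benjamini-Hochberg adjustment was made over the genes of each comparison, and a gene was called at an adjusted p under 0.05. Adjusted p-values in the text are limma's, and for gene lists camera's. There were 19 comparisons: the ipsilateral with the contralateral hemisphere, each hemisphere with sham, day 14 with day 3, 12 with 3 months in sham, and the differences of the hemisphere effect (ipsilateral minus contralateral) between days and between ages. Log2 changes are given with the standard error of limma's moderated model. The share of genes whose arrays did not overlap between the groups is 10% by chance with 3 against 3.

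The sample codes of the 24 stroke samples tie each ipsilateral sample to the contralateral sample of the same replicate number, so that the numbers pair the samples of 12 animals. The codes of stroke replicates differ from animal to animal, whereas the labels do not say that the sham replicates were separate animals; for these the p-values measure only the spread between samples. The deviations of the paired samples from their group means correlated at -0.08 to 0.21, and duplicateCorrelation gave 0.072 over the pairs. The model had no animal term; fits with the animal as a block were alternatives. The codes also carry 1 of 4 numbers whose meaning is not given in the sources used here. One number covers the samples of 3-month rats at day 3, another those at day 14, another the 3-month sham samples, and another the whole of the 12-month samples. At 3 months, comparisons with sham and between days, and the comparison of ages in sham, therefore differ in that number as well as in the group, and the number and the group cannot be told apart. The hemisphere comparisons lie within 1 number, and a shift added to both hemispheres cancels in their differences.

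Gene lists were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives other than those named below as added. The microglial and functional lists were homeostatic microglia, disease-associated microglia, cell cycle, interferon response, pro-inflammatory cytokines and chemokines, alternative activation, lysosome and phagocytosis, complement, antigen presentation, extracellular matrix and proteases, oxidative stress and iron, glycolysis, cholesterol synthesis, oxidative phosphorylation, growth and trophic factors, and immediate early and stress genes. The lists of other cell types were infiltrating monocytes and macrophages, border-associated macrophages, neutrophils, T and NK cells, B cells, astrocytes, oligodendrocytes, oligodendrocyte precursors, neurons, endothelial cells, pericytes and smooth muscle, erythroid cells, and ependyma and choroid plexus. Of 597 entries on the 29 lists, 526 had a named probe set, 10 of them through an older symbol. Lists with at least 5 measured members (28 of them, without erythroid cells) were tested with camera at its preset correlation of 0.01, with adjustment over the lists of a comparison. Camera was repeated with an estimated correlation between the members, and for each list the number of called members is given over the 11675 genes and adjusted over the list alone.

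Named genes followed a rule. For each comparison it took the 8 largest rises and 6 largest falls among called genes whose groups did not overlap, up to 4 called members of each list by the size of the change, and a fixed set of marker genes (P2ry12, Tmem119, Cx3cr1, Spp1, Gpnmb, Apoe, Lpl, Igf1, Lgals3, Top2a, Il1b, Tnf, Arg1, Mrc1, Cd163, Ccr2, S100a8, S100a9, Isg15, Irf7 and Mmp12) whatever their test. Mki67 was in that set but had no probe set that could be tested. Sall1 and Slc2a5, members of the homeostatic list that enter 1 test in the closing section, were taken after their values were seen.

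The alternatives were no filter on dim probe sets, a stricter one (the array's median, which keeps 16582 probe sets), quantile normalization of the deposited values, the mean of a gene's probe sets, testing each kept probe set whether named or not, limma's trend and robust options, the animal as a fixed block or as a random effect, only the arrays of the compared groups, and each replicate left out in turn. Cyclic loess normalization, a fit to the arrays of 1 age and the mean of the 4 hemisphere comparisons were added after seeing the data. The tests were also run on other splits of the samples. The procedure was tested on simulated data with 200 changed genes among 11675, 50 each by 0.3, 0.5, 1 and 2 log2 units. Between hemispheres at 3 months, day 3, it recovered 8, 36, 49 and 50, with 5 false calls. For the hemisphere effect between ages at day 3 it recovered 0, 15, 47 and 50, with 5 false calls. The first comparison had 2384 real calls, so these counts do not give its power or error. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.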

Results

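Microglial RNA from 30 samples was profiled on arrays: 3 samples each of sham, contralateral day 3, ipsilateral day 3, contralateral day 14 and ipsilateral day 14, at 3 and at 12 months of age. The study asked how microglial expression changes from 3 to 14 days after stroke and whether that pattern differs between the ages. Values are log2 signals per array. Changes are differences of group means (n = 3 arrays each) with a standard error pooled over 30 arrays.

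The first 2 principal components over the 11675 tested genes held 37.1% and 29.7% of the variance. The stroke arrays of 3-month rats lay at 3.5 to 37.3 on the first component and the other arrays at -30.0 to -3.6. On the second, the ipsilateral arrays lay at 9.4 to 32.2 and the contralateral and sham arrays at -20.5 to -5.2. The counts of called genes ranged from 1 to 6626 per comparison. Of 28 gene lists, camera called 15, 14, 13 and 7 between hemispheres (3 months days 3 and 14, then 12 months) and 7, 1, 1 and 4 with an estimated correlation. In the same order these numbers were 11, 11, 12 and 9 (0, 2, 1 and 1) for ipsilateral and 13, 7, 5 and 2 (0, 0, 1 and 0) for contralateral samples against sham. They were 10 and 10 (3 and 1) between the days, 14 and 14 (2 and 2) for the difference of hemisphere effects between days, 4 and 7 (1 and 0) for that between ages, and 4 (0) for age in sham.

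**Figure D1:**
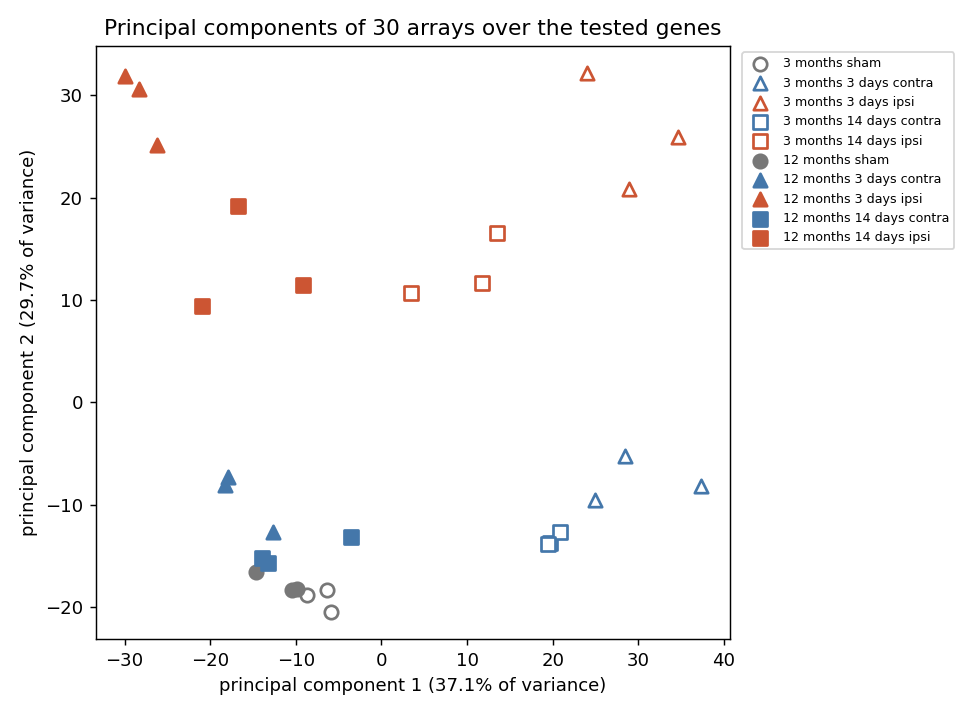
Principal components 1 and 2 of the 30 arrays over the tested genes, with the share of variance on each axis, filled symbols for 12 months and open ones for 3 months. Ipsilateral arrays lie above 9 on component 2, and stroke arrays of 3-month rats to the right on component 1.

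**Figure D2:**
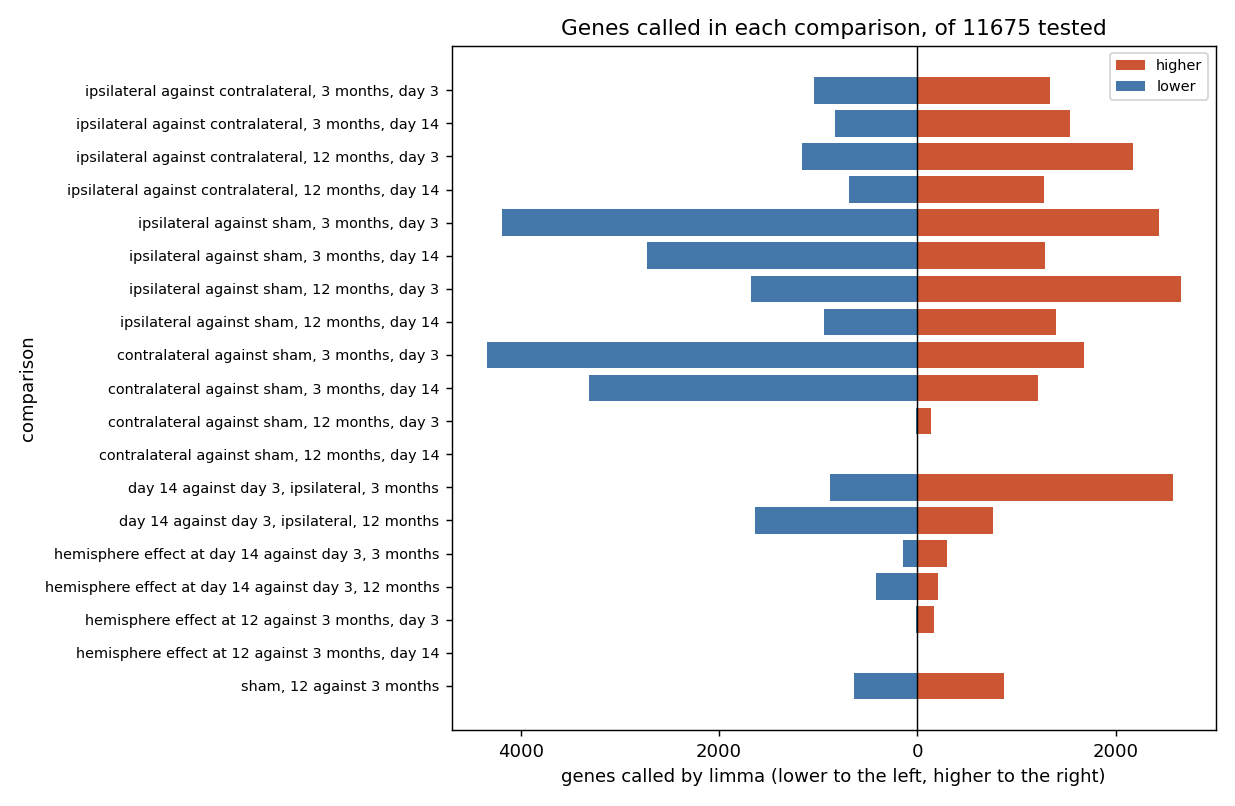
Genes called by limma in each of the 19 comparisons, with lower genes to the left and higher genes to the right of 0. Contralateral samples of 3-month rats differed from sham in 6019 and 4522 genes, and those of 12-month rats in 150 and 1.

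At 3 months and day 3, disease-associated, cell cycle and alternative activation genes rose in microglia of the injured hemisphere against the opposite one, and homeostatic genes fell. Spp1 (osteopontin) rose by 4.76 ± 0.28 log2 units, Lgals3 (galectin-3, a carbohydrate-binding protein) by 3.83 ± 0.23 and Gpnmb (a glycoprotein of phagocytes) by 3.66 ± 0.21. S100a11, a calcium-binding protein, rose by 5.04 ± 0.58 and Il1rn, the interleukin-1 receptor antagonist, by 3.30 ± 0.30. Fabp4, a fatty acid carrier, rose by at least 2.52 (3.27 ± 0.28 as fitted), since its contralateral arrays all lay at or below their 30th percentile. Markers of resting microglia fell, with Tmem119 at -1.52 ± 0.18, the ADP receptors P2ry13 and P2ry12 at -1.08 ± 0.14 and -0.78 ± 0.11, and the fractalkine receptor Cx3cr1 at -0.60 ± 0.08. The cytokine Il6 fell by 1.81 ± 0.19, and Il1b rose by 2.05 ± 0.25 while Tnf fell by 0.64 ± 0.16.

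Of the 24 measured homeostatic genes at 3 months and day 3, 18 fell (18 adjusted over the list alone, camera adjusted p = 1.6e-17). Of the 28 disease-associated genes 17 rose and 3 fell (18 and 3 adjusted over the list alone, adjusted p = 1.4e-11), among them the growth factor Igf1 at 1.81 ± 0.13. Cell cycle genes rose in 18 of 26 cases and fell in 1 (20 and 1 adjusted over the list alone, adjusted p = 6e-11), with the ribonucleotide reductase subunit Rrm2 at 1.45 ± 0.19 and the topoisomerase Top2a at 0.97 ± 0.20. Alternative activation genes rose in 12 of 16 cases (13 adjusted over the list alone, adjusted p = 7.2e-09), with the scavenger receptors Mrc1 at 1.87 ± 0.34 and Cd163 at 1.53 ± 0.26. Arg1 rose by 0.35 and was not called elsewhere between hemispheres. Oxidative phosphorylation genes rose in 23 of 25 cases (24 adjusted over the list alone, adjusted p = 6.7e-18), with the cytochrome oxidase subunit Cox7b at 1.03 ± 0.11. Matrix and protease genes rose in 8 of 18 cases and fell in 1 (9 and 1 adjusted over the list alone, adjusted p = 6.1e-05), among them the protease inhibitor Timp1 at 2.20 ± 0.15. Interferon response genes rose in 12 of 32 cases and fell in 1 (13 and 1 adjusted over the list alone, adjusted p = 2.3e-05, and adjusted p = 0.13 with an estimated correlation). Immediate early genes fell in 12 of 18 cases and rose in 1 (13 and 2 adjusted over the list alone, adjusted p = 2.4e-06, and adjusted p = 0.086 with an estimated correlation).

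Markers of other myeloid cells rose too at 3 months and day 3. Of 18 genes of infiltrating monocytes and macrophages 15 rose (15 adjusted over the list alone, camera adjusted p = 9e-15), with S100a6 at 2.53 ± 0.28, Anxa2 at 2.40 ± 0.22 and Vim at 2.24 ± 0.17. Of 9 genes of border-associated macrophages 7 rose (8 adjusted over the list alone, adjusted p = 1.2e-05, and adjusted p = 0.062 with an estimated correlation), Mrc1 and Cd163 being on this list too. Of 17 neutrophil genes 7 rose (7 adjusted over the list alone, adjusted p = 0.00047, and adjusted p = 0.10 with an estimated correlation), with the calgranulins S100a8 at 2.97 ± 0.51 and S100a9 at 3.02 ± 0.52. In all, limma called 2384 genes (1339 higher, 1045 lower), 185 of them higher and 46 lower by at least 2-fold. The higher share was 56.2%, and 46.2% without contralateral replicate 2 (1006 higher, 1170 lower). The hemispheres did not overlap for 30% of genes (10% by chance).

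At 3 months and day 14, disease-associated genes rose in the injured hemisphere. Apoc1, an apolipoprotein, rose by 3.74 ± 0.37, Clec7a (the receptor dectin-1) by 3.39 ± 0.22 and Pdk4, a kinase that limits pyruvate oxidation, by 3.13 ± 0.18. Serping1, the inhibitor of complement C1, rose by 3.51 ± 0.21 as fitted, from a contralateral mean of 4.23 close to the arrays' 30th percentile (1 of 3 arrays at or below it). Lgals3, Spp1 and Gpnmb rose by 3.71 ± 0.23, 3.57 ± 0.28 and 3.40 ± 0.21, and Igf1 by 2.66 ± 0.13. Alox5, the 5-lipoxygenase of leukotriene synthesis, fell by 2.04 ± 0.15, and Tmem119 fell by 1.36 ± 0.18. Top2a (0.12), Mrc1 (-0.03) and Cd163 (-0.21) were not called, with limma adjusted p-values of 0.74, 0.97 and 0.62.

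Interferon response genes rose in 21 of 32 cases at 3 months and day 14 (24 adjusted over the list alone, camera adjusted p = 2.2e-11, and adjusted p = 0.061 with an estimated correlation). Irf7 rose by 1.32 ± 0.14. The antiviral GTPases Mx1 and Mx2 rose by 2.25 ± 0.21 and 1.70 ± 0.22 from contralateral levels below sham. Lysosome and phagocytosis genes rose in 20 of 30 cases (22 adjusted over the list alone, adjusted p = 2.2e-11, and adjusted p = 0.11 with an estimated correlation), led by the cholesterol exporter Abca1 at 2.25 ± 0.08. Of 28 disease-associated genes 19 rose (19, with 1 fall, adjusted over the list alone, adjusted p = 8.6e-21), and of 24 homeostatic genes 15 fell (15 adjusted over the list alone, adjusted p = 5.3e-11, and adjusted p = 0.13 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 16 cases (9, with 1 rise, adjusted over the list alone, adjusted p = 3.6e-05, and adjusted p = 0.20 with an estimated correlation), with the isomerase Idi1 at -1.45 ± 0.21. Oxidative phosphorylation genes rose in 20 of 25 cases (23 adjusted over the list alone, adjusted p = 1.8e-14, and adjusted p = 0.11 with an estimated correlation). Limma called 0 of 26 cell cycle genes, also adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05; camera gave adjusted p = 0.90. The list's mean change was 0.01, its median -0.02 and camera's direction down.

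Monocyte and macrophage genes rose in 9 of 18 cases and fell in 1 at 3 months and day 14 (9 and 2 adjusted over the list alone, camera adjusted p = 0.013, and adjusted p = 0.52 with an estimated correlation), among them Anxa2 at 1.75 ± 0.22 and Vim at 1.51 ± 0.17. Of the genes tested, limma called 2365 (1537 higher, 828 lower), 139 higher and 31 lower by at least 2-fold, and the hemispheres did not overlap for 29.8% (10% by chance). A fit to the 6 compared arrays alone called 1412.

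At 12 months and day 3, cell cycle genes rose in the injured hemisphere. Spp1 rose by 5.31 ± 0.28, Lgals3 by 3.69 ± 0.23, Gpnmb by 3.54 ± 0.21 and Fabp4 by at least 3.07 (3.53 ± 0.28 as fitted). Timp1, an inhibitor of matrix proteases, rose by 3.21 ± 0.15. The cyclin Ccnb1, Rrm2, the spindle checkpoint kinase Bub1 and the mitotic kinase Plk1 rose by 2.76 ± 0.20, 2.64 ± 0.19, 2.20 ± 0.14 and 2.04 ± 0.13. Il6 (-2.01 ± 0.19), the growth factor Hbegf (-1.65 ± 0.17) and Tmem119 (-1.37 ± 0.18) fell.

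In this comparison at 12 months and day 3, cell cycle genes rose in 23 of 26 cases (23, with 1 fall, adjusted over the list alone, camera adjusted p = 5.1e-22), with Top2a at 1.67 ± 0.20. Homeostatic genes fell in 20 of 24 cases (21 adjusted over the list alone, adjusted p = 4.2e-14, and adjusted p = 0.099 with an estimated correlation). Disease-associated genes rose in 16 of 28 cases and fell in 3 (18 and 3 adjusted over the list alone, adjusted p = 1.4e-07, and adjusted p = 0.069 with an estimated correlation), with Igf1 at 1.95 ± 0.13 and the lipase Lpl at 1.89 or more (2.51 ± 0.29 as fitted, its contralateral arrays all at or below their 30th percentile). Oxidative phosphorylation genes rose in 23 of 25 cases (23 adjusted over the list alone, adjusted p = 5.4e-15, and adjusted p = 0.099 with an estimated correlation). Glycolysis genes rose in 12 of 18, with 1 fall (13 and 1 adjusted over the list alone, adjusted p = 1.8e-05, and adjusted p = 0.15 with an estimated correlation). The glycolytic enzymes Hk3 and Pgk1 rose by 1.35 ± 0.14 and 1.11 ± 0.09. Immediate early genes fell in 10 of 18 cases (10 adjusted over the list alone, adjusted p = 2.6e-06, and adjusted p = 0.13 with an estimated correlation), with the transcription factor Egr2 at -0.88 ± 0.12.

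Genes of monocytes and macrophages rose in 13 of 18 cases at 12 months and day 3 (14, with 2 falls, adjusted over the list alone, camera adjusted p = 1.2e-06, and adjusted p = 0.16 with an estimated correlation), with the purine enzyme Gda at 3.48 ± 0.25, Anxa2 at 3.34 ± 0.22 and the adhesion receptor Cd44 at 2.46 ± 0.22. Border-associated macrophage genes rose in 8 of 9 cases (8 adjusted over the list alone, adjusted p = 6.3e-05, and adjusted p = 0.13 with an estimated correlation), with the folate receptor Folr2 at 2.31 ± 0.25 and Cd163 at 2.23 ± 0.26. S100a8 and S100a9 stood at 1.22 ± 0.51 and 1.26 ± 0.52 and were not called (limma adjusted p of 0.078 and 0.069), though they were in fits to the compared arrays alone or to the arrays of 1 age. Limma called 3346 genes (2178 higher, 1168 lower), 281 higher and 43 lower by at least 2-fold, and 45.9% of genes did not overlap (10% by chance).

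At 12 months and day 14, disease-associated and interferon response genes rose and homeostatic genes fell. Pdk4 rose by 4.02 ± 0.18, Axl (a receptor kinase that binds dying cells through bridging ligands) by 3.58 ± 0.18, Cfd (complement factor D) by 3.25 ± 0.24, Rab7b (a GTPase of late endosomes) by 3.23 ± 0.16 and Igf1 by 3.23 ± 0.13. Gpnmb and Spp1 rose by 3.08 ± 0.21 and 2.89 ± 0.28. Falls were seen for Alox5 (-2.26 ± 0.15), Il6 (-2.17 ± 0.19), the cytokine signalling inhibitor Socs2 (-1.95 ± 0.17) and Tmem119 (-1.38 ± 0.18). Cd163 stood at 0.10 and was not called (limma adjusted p = 0.86).

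Disease-associated genes rose in 17 of 28 cases at 12 months and day 14 (19, with 2 falls, adjusted over the list alone, camera adjusted p = 5.3e-17). Homeostatic genes fell in 17 of 24 cases (18 adjusted over the list alone, adjusted p = 3.2e-16), with P2ry13 at -1.28 and Gpr34 at -1.08 ± 0.13. Interferon response genes rose in 16 of 32 cases (20 adjusted over the list alone, adjusted p = 4.4e-10), with Mx1 at 2.19 ± 0.21 and Irf7 at 1.22 ± 0.14. Cholesterol synthesis genes fell in 10 of 16 cases (10 adjusted over the list alone, adjusted p = 2.7e-08, and adjusted p = 0.058 with an estimated correlation), with Idi1 at -1.78 ± 0.21, the sterol oxidase Msmo1 at -1.54 ± 0.19 and the squalene epoxidase Sqle at -1.35 ± 0.18. Oxidative phosphorylation genes rose in 17 of 25 cases (20 adjusted over the list alone, adjusted p = 6.5e-11, and adjusted p = 0.16 with an estimated correlation). Lysosome and phagocytosis genes rose in 12 of 30 with 2 falls (13 and 4 adjusted over the list alone, adjusted p = 0.00011, and adjusted p = 0.44 with an estimated correlation). Monocyte and macrophage genes rose in 8 of 18 cases and fell in 2 (8 and 2 adjusted over the list alone). Their list was not called (camera adjusted p = 0.056). It was called without ipsilateral replicate 2 (0.021) or 3 (0.018), or contralateral replicate 1 (0.027). Limma called 1965 genes (1271 higher, 694 lower), 150 higher and 50 lower by at least 2-fold, with no overlap for 31.4% (10% by chance).

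**Figure D3:**
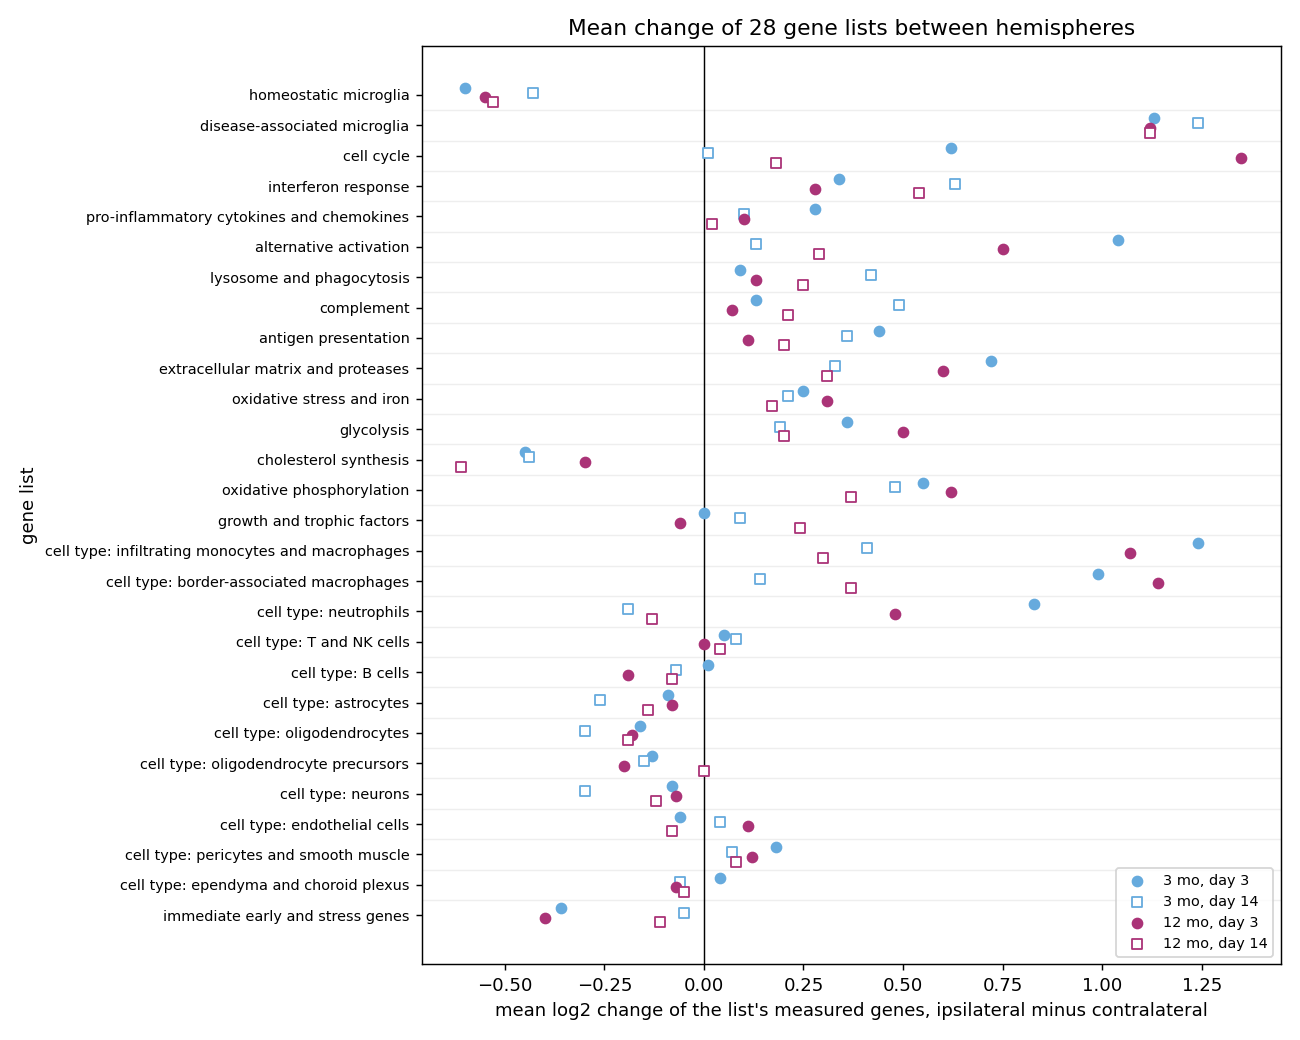
Mean log2 change, ipsilateral minus contralateral, of the measured genes of 28 lists, with 1 point per age and day (circles for day 3, squares for day 14). The cell cycle list lies at 0.62 and 1.35 on day 3 and at 0.01 and 0.18 on day 14, for 3 and 12 months, whereas the homeostatic list lies between -0.60 and -0.43 in the 4 comparisons.

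Across genes, the hemisphere effects of the ages correlated at r = 0.79 on day 3 and 0.81 on day 14, in arrays that shared no sample. On day 3, 1094 genes were higher at both ages, where independent lists would share 249.8, and 608 were lower at both, where they would share 104.5. On day 14 these numbers were 903 against 167.3 and 378 against 49.2. Between days the correlation was 0.64 at 3 months and 0.67 at 12 months. Genes are not independent replicates, so these values describe the arrays at hand.

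Markers of cells outside the myeloid lineage were also compared between the hemispheres. Of the lists of T and NK cells, B cells, oligodendrocyte precursors, endothelial cells, pericytes and smooth muscle, and ependyma and choroid plexus, camera called none in the 4 comparisons, with the lowest adjusted p at 0.078 for oligodendrocyte precursors at 12 months, day 3. That list was called in fits to the compared arrays alone or to the arrays of 1 age (adjusted p = 0.047 in each). At 3 months and day 14, oligodendrocyte genes fell in 3 of 10 cases (5 adjusted over the list alone, adjusted p = 0.0096), astrocyte genes in 4 of 12 (4 adjusted over the list alone, adjusted p = 0.013) and neuronal genes in 2 of 11 (6 adjusted over the list alone, adjusted p = 0.0029). With an estimated correlation these lists had adjusted p = 0.21, 0.40 and 0.30. Without contralateral replicate 1 of that group the adjusted p was 0.089, 0.10 and 0.074, and the neuronal call also ended with the stricter dim filter (0.23).

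In the injured hemisphere of 3-month rats on day 3, set against sham, Spp1 rose by 5.11 ± 0.28, Gpnmb by 4.67 ± 0.21, Lgals3 by 3.93 ± 0.23 and the lipopolysaccharide co-receptor Cd14 by 3.77 ± 0.21. The sterol synthesis enzymes Idi1 (-3.26 ± 0.21), Msmo1 (-2.88 ± 0.19), Fdft1 (-1.89 ± 0.14) and Cyp51 (-1.84 ± 0.15) fell. In all, 13 of 16 genes of that list fell and 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 3.5e-05, and adjusted p = 0.14 with an estimated correlation). Cell cycle genes rose in 21 of 26 cases and fell in 3 (21 and 3 adjusted over the list alone, adjusted p = 2.7e-08, and adjusted p = 0.082 with an estimated correlation). Top2a stood at 2.03 ± 0.20. Homeostatic genes fell in 21 of 24 cases (22, with 1 rise, adjusted over the list alone, adjusted p = 2.7e-07, and adjusted p = 0.16 with an estimated correlation). Monocyte and macrophage genes rose in 11 of 18 cases (11 adjusted over the list alone, adjusted p = 2.7e-07, and adjusted p = 0.14 with an estimated correlation). Border-associated macrophage genes rose in 8 of 9 (8 adjusted over the list alone, adjusted p = 6.2e-06, and adjusted p = 0.082 with an estimated correlation), with Mrc1 at 2.71 ± 0.34 and Folr2 at 2.64 ± 0.25. Limma called 6626 genes (2435 higher, 4191 lower), with no overlap for 61.2% (10% by chance). The higher share of the called genes was 36.7%, and 46.8% after cyclic loess normalization.

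On day 14 at 3 months, the injured hemisphere differed from sham in 4016 genes (1287 higher, 2729 lower; no overlap for 46.5%, 10% by chance). Gpnmb rose by 4.87 ± 0.21, Lgals3 by 3.96 ± 0.23, Axl by 3.91 ± 0.18, Serping1 by 3.63 ± 0.21 as fitted (2 of 3 sham arrays at or below their 30th percentile) and the adhesion molecule Cd34 by 3.46 ± 0.15, and Alox5 fell by 2.71 ± 0.15. Disease-associated genes rose in 19 of 28 cases and fell in 3 (19 and 4 adjusted over the list alone, camera adjusted p = 2.5e-14). Growth and trophic factors rose in 8 of 17 and fell in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.0082), with the cytokines Lif at 1.03 ± 0.17 and Osm at 0.82 ± 0.15. Homeostatic genes fell in 19 of 24 cases (20 adjusted over the list alone, adjusted p = 1.4e-10, and adjusted p = 0.14 with an estimated correlation). Monocyte and macrophage genes rose in 6 of 18 cases and fell in 3 (6 and 3 adjusted over the list alone, adjusted p = 0.018, and adjusted p = 0.72 with an estimated correlation). The higher share of the calls was 32%, and 45% after quantile and 45.9% after loess normalization. Both comparisons with sham at 3 months differ in the number in the sample codes as well, which cannot be told apart from the stroke.

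At 12 months, where sham and stroke samples share 1 number in the codes, the injured hemisphere on day 3 differed from sham in 4328 genes (2655 higher, 1673 lower; no overlap for 53.3%, 10% by chance). Cell cycle genes stood among the largest rises: Rrm2 rose by 4.44 ± 0.19, Top2a by 3.89 ± 0.20, Ccnb1 by 3.76 ± 0.20 and the spindle protein Tpx2 by 3.70 ± 0.14, beside Spp1 at 6.06 ± 0.28. Cell cycle genes rose in 23 of 26 cases and fell in 2 (23 and 2 adjusted over the list alone, camera adjusted p = 3.2e-26). All 25 oxidative phosphorylation genes rose (25 adjusted over the list alone, adjusted p = 3.3e-17, and adjusted p = 0.085 with an estimated correlation), with Cox7b at 1.45 ± 0.11. Immediate early genes fell in 15 of 18 cases (15 adjusted over the list alone, adjusted p = 1.1e-07, and adjusted p = 0.099 with an estimated correlation). Infiltrating cell markers, those of monocytes and macrophages, rose in 14 of 18 cases and fell in 1 (14 and 1 adjusted over the list alone, adjusted p = 2.5e-06, and adjusted p = 0.19 with an estimated correlation), with Anxa2 at 3.67 ± 0.22.

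On day 14 at 12 months, 2339 genes differed from sham (1395 higher, 944 lower; no overlap for 36.3%, 10% by chance). Gpnmb rose by 4.55 ± 0.21, Pdk4 by 4.46 ± 0.18, Axl by 4.28 ± 0.18, Rab7b by 3.89 ± 0.16 and Igf1 by 3.41 ± 0.13, while Alox5 (-2.40 ± 0.15) and Tmem119 (-1.32 ± 0.18) fell. Disease-associated genes rose in 19 of 28 cases and fell in 2 (20 and 3 adjusted over the list alone, camera adjusted p = 1.1e-17). Interferon response genes rose in 18 of 32 cases (19 adjusted over the list alone, adjusted p = 5.3e-10, and adjusted p = 0.066 with an estimated correlation), with Mx1 at 2.17 ± 0.21. Cholesterol synthesis genes fell in 11 of 16 cases (11 adjusted over the list alone, adjusted p = 5e-07, and adjusted p = 0.12 with an estimated correlation), with Msmo1 at -1.30 ± 0.19.

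In the hemisphere opposite the stroke, cell cycle genes rose against sham in 12-month rats on day 3. Top2a rose by 2.21 ± 0.20, Stmn1 (a microtubule regulator) by 2.10 ± 0.25, Rrm2 by 1.79 ± 0.19 and Tpx2 by 1.72 ± 0.14. The mitotic kinase Cdk1 rose by at least 1.25 (1.49 ± 0.16 as fitted), its sham arrays all lying at or below their 30th percentile. Cell cycle genes rose in 18 of 26 cases (23, with 1 fall, adjusted over the list alone, camera adjusted p = 7.2e-56). Oxidative phosphorylation genes rose in 3 of 25 cases (11 adjusted over the list alone, adjusted p = 6e-13, and adjusted p = 0.20 with an estimated correlation). Of 16 cholesterol synthesis genes 1 fell (8 adjusted over the list alone, adjusted p = 1.8e-09, and adjusted p = 0.083 with an estimated correlation). The complement component C3 fell by 0.52 ± 0.10. Limma called 150 genes (135 higher, 15 lower; no overlap for 18%, 10% by chance). The count was 72 and 61 without contralateral replicate 1 or 3, and 89 and 81 without sham replicate 1 or 2. The higher share of the calls was 90%, and 77.9% after loess normalization. On day 14, Gpnmb was the 1 called gene at 12 months, with a rise of 1.47 ± 0.21 (816 genes at an unadjusted p under 0.05; no overlap for 15.3%, 10% by chance). Its limma adjusted p was 0.058 with the trend and robust options, 0.06 without contralateral replicate 2 and 0.062 without sham replicate 2. Of 28 disease-associated genes Gpnmb alone rose there (5 adjusted over the list alone, camera adjusted p = 3.9e-05, and adjusted p = 0.37 with an estimated correlation). Of 25 oxidative phosphorylation genes limma called 0, also adjusted over the list alone (2 higher at an unadjusted p under 0.05), while camera called the list upward (adjusted p = 0.015, and adjusted p = 0.94 with an estimated correlation). The latter call ended after quantile (0.12) and loess normalization (0.20), without contralateral replicate 2 or 3 (0.19 and 0.22) and without sham replicate 1 or 2 (0.21 and 0.32).

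At 3 months the contralateral samples differed from sham in 6019 genes on day 3 (1676 higher, 4343 lower) and in 4522 on day 14 (1212 higher, 3310 lower), with no overlap for 57.7% and 45.5% of genes (10% by chance). Sterol synthesis genes fell on day 3, with Idi1 at -1.67 ± 0.21, Msmo1 at -1.60 ± 0.19 and Fdft1 at -1.38 ± 0.14. Of the list's 16 members 11 fell (13 adjusted over the list alone, camera adjusted p = 0.004, and adjusted p = 0.38 with an estimated correlation). Interferon response genes fell in 20 of 32 cases on day 3 (20 adjusted over the list alone, adjusted p = 0.0095, and adjusted p = 0.38 with an estimated correlation), with Mx2 at -1.34 ± 0.22 and Ifit3 at -1.31 ± 0.22. On day 14 they fell in 18 cases and rose in 1 (18 and 1 adjusted over the list alone, adjusted p = 0.0057, and adjusted p = 0.46 with an estimated correlation), with Mx2 at -1.23 ± 0.22 and Mx1 at -1.15 ± 0.21. The interferon call ended with the stricter dim filter (adjusted p = 0.14 and 0.097) and, on day 14, without sham replicate 2 (0.054). Gpnmb rose by 1.48 ± 0.21 on day 14, and Top2a by 1.06 ± 0.20 on day 3.

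Oxidative phosphorylation genes fell in 23 of 25 cases on day 3 (23 adjusted over the list alone, camera adjusted p = 0.0024, and adjusted p = 0.42 with an estimated correlation) and in 16 on day 14 (18 adjusted over the list alone, adjusted p = 0.00021, and adjusted p = 0.46 with an estimated correlation) in these 3-month contralateral samples. The list call ended with quantile (0.34 and 0.22) and with loess normalization (0.41 and 0.37). Neuronal genes rose in 7 of 11 cases on day 14 (7 adjusted over the list alone, adjusted p = 0.0012, adjusted p = 0.40 with an estimated correlation, and 0.056 after loess normalization), and border-associated macrophage genes in 5 of 9 on day 3 (5 adjusted over the list alone, adjusted p = 0.0095, and adjusted p = 0.38 with an estimated correlation). The change of a gene correlated with its mean level across genes at r = -0.48 on day 3 and -0.51 on day 14, against 0.11 and 0.04 at 12 months. Of the dimmest 3892 genes 1077 were higher and 224 lower on day 3, and of the brightest 137 were higher and 2651 lower. The higher share of the calls was 27.8% on day 3 (40.4% after quantile, 44.4% after loess normalization, and 17.4% with the stricter dim filter, at 907 higher and 4308 lower) and 26.8% on day 14 (38.2% and 39.9%), and the day 14 count was 2669 and 2694 after these scalings. The 3-month sham samples carry their own number in the codes, so these differences cannot be told apart from that number.

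Within the injured hemisphere of 3-month rats, cell cycle, alternative activation and border-associated macrophage genes were lower on day 14 than on day 3. Serping1 rose by 3.22 ± 0.21, the complement component C3 by 2.40 ± 0.10, the checkpoint receptor Lag3 by 2.35 ± 0.14 and Axl by 1.97 ± 0.18. Falls were seen for S100a8 (-3.17 ± 0.51), S100a9 (-3.06 ± 0.52), Mrc1 (-2.60 ± 0.34), Cd163 (-2.18 ± 0.26) and Rrm2 (-2.04 ± 0.19). Cell cycle genes fell in 19 of 26 cases and rose in 1 (19 and 2 adjusted over the list alone, camera adjusted p = 1.5e-17). Alternative activation genes fell in 12 of 16 and rose in 1 (13 and 1 adjusted over the list alone, adjusted p = 5.7e-11). Border-associated macrophage genes fell in 8 of 9 (8, with 1 rise, adjusted over the list alone, adjusted p = 3e-09). Of 18 genes of infiltrating monocytes and macrophages 12 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 4.6e-09, and adjusted p = 0.11 with an estimated correlation). Of 17 neutrophil genes 7 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.00012, and adjusted p = 0.099 with an estimated correlation). Complement genes went both ways, with 5 of 14 higher and 6 lower (6 and 6 adjusted over the list alone, adjusted p = 0.74); their mean was 0.20, their median -0.08 and camera's direction down. Interferon response genes rose in 19 of 32 cases and fell in 1 (21 and 1 adjusted over the list alone, adjusted p = 0.00067, and adjusted p = 0.39 with an estimated correlation). Limma called 3451 genes (2574 higher, 877 lower; no overlap for 40.1%, 10% by chance). The higher share was 74.6%, and 59.9% after quantile and 55.9% after loess normalization; the number in the codes differs between the days here.

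At 12 months, 2404 genes differed between the days (762 higher, 1642 lower; no overlap for 37.8%, 10% by chance). Axl rose by 2.84 ± 0.18, Rab7b by 2.67 ± 0.16, Lag3 by 2.45 ± 0.14, C3 by 2.01 ± 0.10, and the antigen presentation genes Cd74 and RT1-Da by 2.10 ± 0.43 and 2.04 ± 0.57. Rrm2 (-4.04 ± 0.19), Ccnb1 (-3.48 ± 0.20), Top2a (-3.45 ± 0.20) and Spp1 (-2.82 ± 0.28) fell. Cell cycle genes fell in 23 of 26 cases (24, with 1 rise, adjusted over the list alone, camera adjusted p = 4.1e-44). Oxidative phosphorylation genes fell in 22 of 25 cases (23, with 1 rise, adjusted over the list alone, adjusted p = 1.5e-09, and adjusted p = 0.26 with an estimated correlation). Those of monocytes and macrophages fell in 11 of 18 cases and rose in 1 (13 and 1 adjusted over the list alone, adjusted p = 1.1e-05, and adjusted p = 0.30 with an estimated correlation), with Cd163, on the list of border-associated macrophages, at -2.11 ± 0.26.

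**Figure D4:**
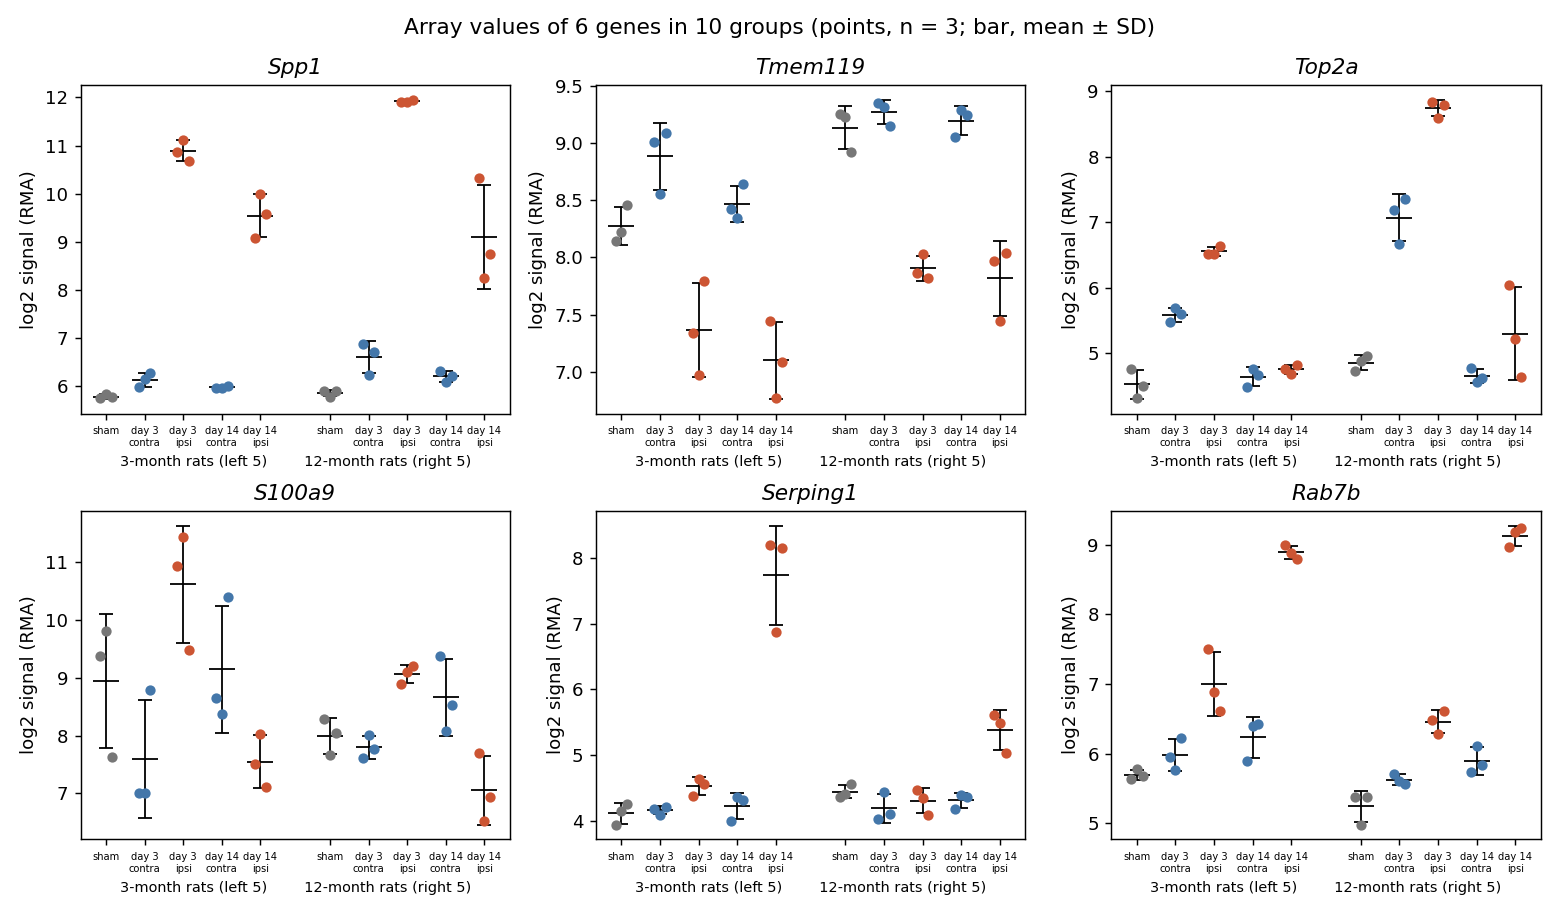
Log2 signal of Spp1, Tmem119, Top2a, S100a9, Serping1 and Rab7b on each array (points), with the mean and SD of each group of 3 (bars), for sham, contralateral and ipsilateral samples at both days and ages. Serping1 lay at 6.87 to 8.20 in the injured hemisphere on day 14 at 3 months, at 5.03 to 5.61 at 12 months, and near the 30th percentile of the arrays (4.07 to 4.35) in the opposite one.

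The difference of the hemisphere effect between days was tested itself, with higher and lower referring to the signed effect. At 3 months the effect was higher on day 14 for Cd34 (1.92 ± 0.21), Lag3 (1.89 ± 0.20), Pdk4 (1.88 ± 0.26), C3 (1.61 ± 0.14) and Axl (1.57 ± 0.26). Serping1 was higher too (3.16 ± 0.29 as fitted), but its contralateral arrays lay at or below their 30th percentile in 3 of 3 cases on day 3 and 1 of 3 on day 14, so the size is open. The effect was lower on day 14 for S100a9 (-4.61 ± 0.74), S100a8 (-4.42 ± 0.73), the protease inhibitor Slpi (-3.48 ± 0.53) and Rrm2 (-1.66 ± 0.26). S100a9 and S100a8 had turned, from 3.02 and 2.97 on day 3 to -1.59 ± 0.52 and -1.45 ± 0.51 on day 14 (limma adjusted p = 0.029 and 0.045). Without contralateral replicate 3 these day 14 values were -0.96 and -0.84 and not called (0.23 and 0.30), nor were they with the trend and robust options (0.075 and 0.10). Cell cycle genes had a lower effect on day 14 in 13 of 26 cases and a higher one in 1 (17 and 1 adjusted over the list alone, camera adjusted p = 7.4e-14), and alternative activation genes in 7 and 1 of 16 (13 and 1 adjusted over the list alone, adjusted p = 1.7e-10). Markers of other macrophages moved with the latter, Mrc1 and Cd163 being shared. The mean effect of monocyte and macrophage genes went from 1.24 to 0.41, lower in 7 of 18 cases (12, with 1 higher, adjusted over the list alone, adjusted p = 5.8e-10, and adjusted p = 0.099 with an estimated correlation). That of border-associated macrophage genes went from 0.99 to 0.14, lower in 3 of 9 (6, with 1 higher, adjusted over the list alone, adjusted p = 3.1e-05, and adjusted p = 0.099 with an estimated correlation). Lysosome and phagocytosis genes had a higher effect in 11 of 30 cases and a lower one in 1 (18 and 1 adjusted over the list alone, adjusted p = 1.1e-12, and adjusted p = 0.054 with an estimated correlation), with Abca1 at 1.16 ± 0.12. Neutrophil genes had a lower effect in 4 of 17 cases (4 adjusted over the list alone, adjusted p = 2.2e-06, and adjusted p = 0.054 with an estimated correlation). Limma called 445 genes (300 higher, 145 lower; no overlap for 19.2%, 10% by chance). The count was 269 without replicate 1 of day 14, 252 without replicate 1 of day 3, 141 in a fit to the compared arrays alone and 232 in a fit to the arrays of that age. Without replicate 3 of day 3, 257 were higher and 200 lower, a higher share of 56.2% against 67.4%.

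At 12 months the hemisphere effect differed between days in 623 genes (204 higher on day 14, 419 lower; no overlap for 23.9%, 10% by chance). It was higher on day 14 for Rab7b (2.40 ± 0.23), Axl (2.30 ± 0.26), the chemokine Cxcl13 (1.83 ± 0.37) and Igf1 (1.27 ± 0.18), and lower for Gda (-2.64 ± 0.35), Ccnb1 (-2.57 ± 0.28), Spp1 (-2.42 ± 0.39) and Cd163 (-2.13 ± 0.36). Cell cycle genes had a lower effect on day 14 in 21 of 26 cases (23 adjusted over the list alone, camera adjusted p = 3.4e-36). Monocyte and macrophage genes had a lower one in 6 of 18 and a higher one in 1 (8 and 1 adjusted over the list alone, adjusted p = 9.7e-06, and adjusted p = 0.27 with an estimated correlation), and border-associated macrophage genes a lower one in 3 of 9 (4, with 1 higher, adjusted over the list alone, adjusted p = 0.00071, and adjusted p = 0.27 with an estimated correlation). Growth and trophic factors had a higher one in 3 of 17 (5 adjusted over the list alone, adjusted p = 0.00071), with Gdf15 at 1.14 ± 0.21 and Osm at 0.99 ± 0.21. The split of the calls was 32.7% higher, and 43.6% after quantile normalization. Without 1 animal the count was 360 and 341 (day 14, replicates 2 and 3) and 406, 403 and 383 (day 3, replicates 1 to 3).

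Between the ages, the hemisphere effect on day 3 differed in 184 genes (166 higher at 12 months, 18 lower; 1519 at an unadjusted p under 0.05; no overlap for 20.1%, 10% by chance), cell cycle genes among them. Spc25, a kinetochore protein, differed by 1.77 ± 0.18 and Cdc20 by 1.23 ± 0.20, beside Pdk4 at 1.73 ± 0.26 and the tight junction protein Tjp1 at 1.68 ± 0.21. Cell cycle genes had a higher effect at 12 months in 12 of 26 cases (23 adjusted over the list alone, camera adjusted p = 4.7e-23). Over the 21 of them above the 30th percentile on all 12 arrays, the mean difference was 0.69 with a standard error over members of 0.09. Monocyte and macrophage genes had a mean difference of -0.17 (camera adjusted p = 0.089), with 0 of 18 called by limma over the tested genes (2 higher and 1 lower adjusted over the list alone). The camera p of that list fell to 0.039 without 12-month replicate 3 and to 1.2e-05 without 3-month replicate 3. Camera also called lower effects for alternative activation, neutrophil and pro-inflammatory cytokine genes (adjusted p = 0.039 each, and adjusted p = 0.63 each with an estimated correlation). Of their 16, 17 and 24 members limma called 0, 0 and 1, lower (4, 0 and 1 adjusted over the list alone; 5, 4 and 4 at an unadjusted p under 0.05). Those calls ended without 12-month replicate 1 (0.077, 0.15 and 0.15) or 3-month replicate 2 (0.11, 0.12 and 0.39), the first also without 12-month replicate 2 (0.13) and the first pair without 3-month replicate 1 (0.60 and 0.21) or with the stricter dim filter (0.13 and 0.078). The count of 184 was 79, 94 and 104 without 12-month replicates 1 to 3, and 106 after quantile normalization. Without 3-month replicate 3 it was 143, of which 88 were higher and 55 lower.

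On day 14, Serping1 was the 1 gene whose hemisphere effect was called different between the ages: its effect at 12 months minus that at 3 months was -2.44 ± 0.29 as fitted (1045 genes at an unadjusted p under 0.05; no overlap for 12.8%, 10% by chance). Its ipsilateral means were 5.38 ± 0.31 and 7.74 ± 0.75 (SD, n = 3) and its contralateral means 4.31 and 4.23, the latter close to the 30th percentile (1 of 3 arrays at or below it at each age), so the size of each hemisphere effect is open. Counts there were 4 without 12-month replicate 2, 4 and 5 without 3-month replicate 1 or 2, and 2 in a fit to the compared arrays alone. Camera called 7 lists at the preset correlation. Lysosome and phagocytosis genes had a mean difference of -0.17, with 0 of 30 called by limma (1 lower adjusted over the list alone, 8 lower at an unadjusted p under 0.05; camera adjusted p = 9.5e-06, and adjusted p = 0.53 with an estimated correlation). Of 14 complement genes Serping1 alone was lower (2 adjusted over the list alone, adjusted p = 0.0072, and adjusted p = 0.53 with an estimated correlation). In the other lists limma called 0 of 26 cell cycle, 17 growth factor, 11 neuronal, 24 homeostatic and 25 oxidative phosphorylation genes (0, 2, 0, 0 and 0 adjusted over the list alone). At an unadjusted p under 0.05, 2, 2 and 2 of the first lists were higher, and 4 and 2 of the last were lower. Camera adjusted p for these was 0.016, 0.025, 0.037, 0.037 and 0.037, and with an estimated correlation adjusted p = 0.70, 0.15, 0.70, 0.76 and 0.76. After loess normalization none of the 7 was called (adjusted p = 0.11 to 0.89), and each but the lysosomal list lost its call without at least 1 animal: cell cycle without 12-month replicate 1 (0.20) or 3-month replicate 2 (0.21), complement without 12-month replicate 2 or 3 (0.054 and 0.061), and growth factors without 12-month replicate 3 (0.067) or 3-month replicate 1 or 3 (0.055 and 0.094). Neuronal genes lost it without 12-month replicate 2 or 3 (0.25 and 0.067) or 3-month replicate 1 (0.84), and homeostatic genes without 12-month replicate 2 (0.34) or 3-month replicate 1 or 3 (0.47 and 0.075). Oxidative phosphorylation genes lost it without 12-month replicate 2 or 3 (0.36 and 0.17) or 3-month replicate 1 or 2 (0.055 and 0.23). The neuronal, homeostatic and oxidative phosphorylation calls also ended after quantile normalization (0.08, 0.55 and 0.52) and with the stricter dim filter (0.67, 0.10 and 0.10). With the replicate block the homeostatic call ended (0.053) and one of lower cholesterol synthesis genes was added (0.023). Age differs together with the number in the codes, and a shift added to both hemispheres cancels in these differences.

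In sham microglia 1516 genes differed between 12 and 3 months (872 higher, 644 lower; no overlap for 33.8%, 10% by chance). The glutamate transporter Slc1a3 was higher at 12 months by at least 2.77 (2.90 ± 0.21 as fitted, its 3-month arrays all at or below their 30th percentile), the matrix protein Chad by 2.04 ± 0.15, Tmem119 by 0.86 ± 0.18, C3 by 0.84 ± 0.10 and the apolipoprotein Apoe by 0.59 ± 0.09, whereas Pdk4 was lower (-1.95 ± 0.18), as were the chromatin methyltransferase Ezh2 (-1.52 ± 0.13) and Igf1 (-0.99 ± 0.13). Interferon response genes were lower in 9 of 32 cases and higher in 1 (13 and 2 adjusted over the list alone, camera adjusted p = 0.00081, and adjusted p = 0.85 with an estimated correlation), with Mx2 at -1.08 ± 0.22. Lysosome and phagocytosis genes were higher in 10 of 30 cases (12, with 1 lower, adjusted over the list alone, adjusted p = 0.01, and adjusted p = 0.97 with an estimated correlation). Complement genes were higher in 6 of 14 cases (6 adjusted over the list alone, adjusted p = 0.023, and adjusted p = 0.85 with an estimated correlation), a call lost without 3-month sham replicate 3 (0.051) and in a fit to the compared arrays alone (0.13). The count of 1516 was 848 and 974 without 12-month sham replicate 2 or 3, and 902 and 872 without 3-month replicate 1 or 2. The higher share was 57.5%, and 69% after quantile normalization. It was 43.3% over single probe sets (1247 higher, 1633 lower). Age and the number in the sample codes cannot be told apart in this comparison.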

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

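The tests of the number in the sample codes, of the monocyte genes and of dilution by other cells, cyclic loess normalization as an alternative, the fit to the arrays of 1 age, the mean of the 4 hemisphere comparisons, and the look at arrays near the dim filter's percentile were chosen only after the result each bears on was seen. The results below stand out because the hemisphere effect itself differed between days or between ages in limma's test of that difference.

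At 3 months 445 genes had a hemisphere effect that differed between day 14 and day 3. The largest differences upward were the adenylate kinase Ak4 (2.07), Cd34 (1.92), Lag3 (1.89), Pdk4 (1.88), Rab7b (1.63), C3 (1.61) and the arginine transporter Slc7a2 (1.57), in log2 units. Serping1 (3.16 as fitted) is not ranked, since its contralateral arrays lay at or below their 30th percentile in 3 of 3 cases on day 3 and 1 of 3 on day 14. The largest downward were S100a9 (-4.61), S100a8 (-4.42), Slpi (-3.48), Acod1, the enzyme that makes itaconate (-2.72), S100a6 (-2.64) and Lrg1 (-2.42). Acod1 was not called in a fit to the compared arrays alone (adjusted p = 0.089). The cell cycle list had a mean difference of -0.61 and the alternative activation list of -0.91. The count of 445 was 269 without replicate 1 of day 14 and 252 without replicate 1 of day 3.

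At 12 months 623 genes had an effect that differed between the days, 360 and 341 without replicates 2 and 3 of day 14, and 406, 403 and 383 without replicates 1 to 3 of day 3. The largest differences upward were Rab7b (2.40), Axl (2.30), Cxcl13 (1.83), Lag3 (1.78), Coro6 (1.65), Aebp1 (1.62), the kinase Fyn (1.60) and Cd72 (1.57), and the largest downward were S100a11 (-3.07), S100a9 (-2.87), Gda (-2.64), Ccnb1 (-2.57), S100a8 (-2.56) and Spp1 (-2.42). The calls of S100a11, S100a9 and S100a8 ended with limma's trend and robust options (adjusted p = 0.075, 0.06 and 0.095). S100a11 also lost its call without replicates 2 and 3 of day 14 (0.088 and 0.082) and 1 and 3 of day 3 (0.075 and 0.11), and with the mean of its probe sets (0.054). S100a9 lost it without replicate 3 of day 14 (0.065) and without replicates 1 to 3 of day 3 (0.059, 0.051 and 0.074), and S100a8 without replicates 1 to 3 of day 14 (0.079, 0.073 and 0.09) and of day 3 (0.074, 0.13 and 0.11). The mean difference was -1.17 for the cell cycle list and 0.30 for growth and trophic factors.

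Between the ages, 184 genes differed in their hemisphere effect on day 3, 79, 94 and 104 without 12-month replicates 1 to 3. Without 3-month replicate 3 there were 143, 88 of them higher and 55 lower. Upward these were led by Spc25 (1.77), Pdk4 (1.73), Tjp1 (1.68), the linker histone H1f5 (1.61), Aspm (1.5), Ska3 (1.49) and Ccnb1 (1.49), and the cell cycle list had a mean difference of 0.73. Kif4a (1.52 as fitted) is not ranked, since its 3-month arrays lay at or below their 30th percentile in 3 of 3 contralateral and 2 of 3 ipsilateral cases. Ccnb1 was not called after quantile normalization (1.10, adjusted p = 0.061). Downward were Nr4a3 (-0.86), the chemokine Ccl2 (-0.84), the cell cycle inhibitor Cdkn1a (-0.81), Gas7 (-0.74), Garin4 (-0.74) and Mxd1 (-0.74). Without 12-month replicates 1, 2 and 3 in turn, the adjusted p was 0.11, 0.13 and 0.11 for Nr4a3, 0.10, 0.20 and 0.084 for Ccl2, and 0.11, 0.25 and 0.10 for Cdkn1a. Without 3-month replicates 1 and 2 it was 0.11 and 0.053 for Nr4a3, 0.16 and 0.084 for Ccl2 (0.092 without replicate 3), and 0.058 and 0.091 for Cdkn1a. Gas7 lost its call without replicates 1 and 2 of 12 months (0.096 and 0.11) and of 3 months (0.11 and 0.12). Garin4 lost it without 12-month replicates 1 and 2 (0.15 and 0.19) and 3-month replicates 2 and 3 (0.088 and 0.19). Mxd1 lost it without 12-month replicate 2 (0.26) and 3-month replicates 1 and 2 (0.17 and 0.11). On day 14 the 1 gene was Serping1 (-2.44 as fitted, with 1 of 3 contralateral arrays at or below the percentile at each age), and counts were 4 without 12-month replicate 2, and 4 and 5 without 3-month replicates 1 and 2. Camera called 7 of 28 lists there, and 0 with an estimated correlation.

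The larger cell cycle effect at 12 months on day 3 had a slope of 1.87 over the list (12-month against 3-month effect). A flattened 3-month signal would give other changed genes a like slope. Over 131 genes outside the list, changed at least 2-fold on day 14 at both ages, the slope was 0.99. Over 72 genes outside the list but as dim (contralateral level 4.91 to 6.26), so changed at 1 or both ages, it was 1. This test was fixed after the first slope was seen. The standard errors, over genes and not animals, were 0.03 and 0.04. A larger share of infiltrating monocytes and macrophages at 12 months would raise their markers, whose mean difference was -0.17 with a standard error over members of 0.14, and 5 of 18 above 0. The design's own difference, age, stays open and was not tested apart from the number in the codes.

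The 6019 and 4522 calls between contralateral and sham samples at 3 months went with array values that spread less than on the other arrays. Giving the arrays 1 distribution by quantile normalization left 4539 calls on day 3 and 2669 on day 14, which argues against that spread as the whole cause. The change followed the signal level (r = -0.48 and -0.51). The latter was past the bound set for a level trend, the former between the bounds for and against one. With such trends removed by loess, 4312 and 2694 genes were called, 3144 and 2044 of them shared. This, and not the correlations, argues against the trend as the whole cause. At 12 months, where sham and stroke samples share 1 number in the codes, the counts were 150 and 1, and the 3-month and 12-month changes correlated at r = 0 and 0.04 across genes. A batch tied to the number may account for the 3-month counts, and it cannot be told apart from a response of young rats because each of these groups has its own number.

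The fall of homeostatic genes in the injured hemisphere might come from dilution of microglia by other cells, which would lower genes restricted to microglia by 1 amount. Of P2ry12, Tmem119, Sall1, Gpr34 and Slc2a5, those over 2 standard errors from the median change numbered 1 and 1 at 3 months (days 3 and 14; medians -0.79 and -0.47), and 2 and 3 at 12 months (medians -0.64 and -0.79). The 3 genes of the last comparison were Gpr34 (-1.08), Sall1 (-0.48) and Tmem119 (-1.38). The number of genes that would count against dilution was set, and Sall1 and Slc2a5 were taken, after these values were seen, so the counts exclude nothing. Dilution stays open in the 4 comparisons beside a change of microglial state, which was not tested apart from it.

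For each of the 19 comparisons, the real grouping was the 1 of 10 splits of 3 against 3 with as many calls, and 10 splits cannot give a share under 0.1. Between hemispheres (3 months days 3 and 14, then 12 months) the real counts were 2384, 2365, 3346 and 1965 and the highest of the other splits 20, 8, 1 and 10; among splits that parted each animal's samples, the highest were 1, 3, 1 and 0. In the same order, ipsilateral against sham gave 6626, 4016, 4328 and 2339, with 0, 0, 0 and 1 as the highest other, and contralateral against sham gave 6019, 4522, 150 and 1, with 0, 3, 2 and 0. Day 14 against day 3 gave 3451 and 2404 (highest other 58 and 5), the differences of the hemisphere effect between days 445 and 623 (1 and 1) and between ages 184 and 1 (0 and 0), and age in sham 1516 (0). For the mean of the 4 hemisphere comparisons, limma called 5053 genes (2849 higher, 2204 lower). Of 100 drawn swaps of hemispheres within animals, the real one included, 1 gave as many (highest other 2901). This argues against chance for that mean.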

How the results depend on the processing

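Cyclic loess normalization and the fit to the arrays of 1 age were chosen only after the data were seen. Of 309 counts of calls under the alternatives, 265 lay within 1.5 times the reported one, 27 below and 17 above. Of 25498 values for named genes, 23843 stayed on their side of the threshold, 1544 lost the call, 106 gained one and 5 reversed. Of 7588 for gene lists these were 7048, 355, 181 and 4. A change of direction was counted only for values called in the reported fit or the alternative (else counted as unchanged). Signal near background limits dim genes: the filter asked for 3 arrays above the 30th percentile, and 1160 of the 11675 genes had a group with all arrays at or below it. Except where the number tested shows it, the cause was not tested.

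Testing each of 22343 probe sets, more than the number of genes, raised the counts: 3780 and 3714 between hemispheres at 3 months (days 3 and 14) and 5218 at 12 months, day 3; 12198, 7419, 7106 and 3598 for ipsilateral against sham; 11008, 8210 and 3 for contralateral against sham (3 months days 3 and 14, 12 months day 14); 5455 for day 14 against day 3 at 3 months; and 2880 for age in sham. Quantile normalization gave 2669 for contralateral against sham at 3 months, day 14, and 106 for the difference between ages on day 3, and loess gave 2694 for the former. For contralateral against sham at 12 months, day 14, limma's trend and robust options called 0 genes (1 in the reported fit, 816 at an unadjusted p under 0.05). With fewer arrays in the fit, the compared groups alone gave 1412 between hemispheres at 3 months, day 14, 2 for contralateral against sham at 12 months, day 14, 141 for the difference between days at 3 months and 2 for that between ages on day 14, and the arrays of 1 age gave 232 for the difference between days at 3 months.

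With 1 replicate left out, contralateral against sham gave 61 to 207 at 12 months, day 3, and 0 to 1 on day 14 (0 without contralateral replicate 2 or sham replicate 2). The difference of hemisphere effects gave 252 to 457 and 341 to 574 between days (3 and 12 months), and 79 to 143 and 1 to 5 between ages (days 3 and 14). Age in sham gave 848 to 1227. The hemisphere counts stayed at 1798 to 2176, 1840 to 2183, 2551 to 3113 and 1418 to 1723. A group left with 2 arrays kept the pooled spread.

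With the animal as a fixed replicate block, the hemisphere counts were 2260, 2232, 3257 and 1891, and the differences between them 365, 568, 148 and 1; with the animal as a random effect they were 2537, 2584, 3532 and 2131, and 545, 694, 251 and 1. No count moved by over 1.5 times through this pairing. Among gene lists the block ended 5 calls and added 3, and among named genes it ended 24 and added 2.

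Directions reversed for 4 genes. Against sham, contralateral Mbp at 3 months, day 3, went to 0.28 with the mean of probe sets and 0.02 with loess, Psmb9 there to 0.02 with loess, C1qa on day 14 to 0.04 with loess, and ipsilateral Apoe at 12 months, day 3, to -0.24 with loess. The lysosome and phagocytosis list turned from lower to higher for contralateral against sham at 3 months, day 3, with quantile (adjusted p = 0.018) and loess normalization (0.0018), and on day 14 with loess (0.41), as did immediate early and stress genes on day 14 (0.031). Camera with an estimated correlation ended 155 list calls.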

Other observations

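Cyclic loess normalization, used below, was chosen only after the data were seen.

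Cytokine genes moved both ways between the hemispheres. Il1b rose in all 4 comparisons, by 2.05 ± 0.25 and 1.23 ± 0.25 at 3 months (days 3 and 14) and by 1.12 ± 0.25 and 1.77 ± 0.25 at 12 months. Il1rn, which blocks the receptor of that cytokine, rose by 2.31 ± 0.30 at 3 months, day 14, and by 2.85 ± 0.30 and 2.44 ± 0.30 at 12 months. Tnf fell in each, at -0.64 ± 0.16 and -0.93 ± 0.16, then -0.77 ± 0.16 and -1.11 ± 0.16. Of 24 genes on the list of pro-inflammatory cytokines and chemokines, 9, 5, 8 and 7 rose (9, 6, 9 and 9 adjusted over the list alone) and 6, 5, 6 and 7 fell (6, 5, 6 and 7). Camera did not call the list (adjusted p = 0.25, 0.87, 0.86 and 0.53). At 12 months its mean was positive (0.10 and 0.02), its median negative (-0.04 and -0.14) and camera's direction down. Genes of oxidative stress and iron rose in 10, 7, 11 and 7 of 22 cases and fell in 2, 2, 1 and 4 (10, 9, 12 and 7 against 2, 3, 1 and 4 adjusted over the list alone). The peroxidase Prdx1 rose by 1.12 ± 0.14, 0.87 ± 0.14, 1.23 ± 0.14 and 0.64 ± 0.14, and the mitochondrial dismutase Sod2 by 0.82 ± 0.12, 0.67 ± 0.12, 0.70 ± 0.12 and 0.67 ± 0.12. Camera adjusted p was 0.0022, 0.028, 0.0068 and 0.095, and with an estimated correlation adjusted p = 0.19, 0.45, 0.28 and 0.62. After loess normalization the calls at 3 months, day 14 (0.25) and 12 months, day 3 (0.074) ended. The former also ended after quantile normalization (0.094), with the stricter dim filter (0.097) and without contralateral replicate 2 (0.085).

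Complement, antigen presentation and growth factor genes were also compared between the hemispheres. On day 14, Cd59b, which restrains the membrane attack complex, rose by 1.23 ± 0.14 at 3 months and by 1.56 ± 0.14 at 12 months, C1r, a protease of the classical pathway, rose by 1.41 ± 0.12 and 1.06 ± 0.12, and properdin (Cfp) fell at -1.31 ± 0.17 and -1.19 ± 0.17. Complement genes rose in 3, 6, 3 and 6 of 14 cases and fell in 2 of each (5, 6, 3 and 6 against 2, 3, 2 and 4 adjusted over the list alone). Camera called the complement list at 3 months, day 14 (adjusted p = 0.0027, and adjusted p = 0.21 with an estimated correlation), but not after quantile (0.055) or loess normalization (0.082). Elsewhere adjusted p was 0.51, 0.98 and 0.13. Antigen presentation genes rose in 8, 6, 7 and 4 of 22 cases and fell in 2, 1, 2 and 1 (14, 7, 8 and 4 against 2, 1, 2 and 1 adjusted over the list alone). The thiol reductase Ifi30 rose by 0.80 ± 0.11 at 3 months, day 14, and by 0.82 ± 0.11 and 0.77 ± 0.11 at 12 months. Camera adjusted p was 0.0021, 0.0087, 0.23 and 0.11, and with an estimated correlation adjusted p = 0.38, 0.52, 0.76 and 0.63. Without ipsilateral replicate 1 the call at 3 months, day 3 ended (0.11). Growth and trophic factors were called at 12 months, day 14, with 7 of 17 higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.02, and adjusted p = 0.048 with an estimated correlation). Gdf15 rose by 1.27 ± 0.15, Fgf2 by 0.88 ± 0.15 and Vegfb by 0.70 ± 0.09. That call ended with the stricter dim filter (0.054) and without contralateral replicate 3 (0.078).

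Among markers of other cells, Cd8a of T cells rose by 0.80 ± 0.17 and 0.95 ± 0.17 at 3 months and by 0.83 ± 0.17 and 0.89 ± 0.17 at 12 months. Its list of T and NK cells had 1, 2, 1 and 2 of 14 genes higher and 1, 1, 2 and 0 lower (1, 2, 1 and 2 against 1, 1, 2 and 1 adjusted over the list alone). Anpep, an aminopeptidase on the list of pericytes and smooth muscle that myeloid cells also express, rose by 2.92 ± 0.37, 1.96 ± 0.37, 2.46 ± 0.37 and 1.59 ± 0.37. It was the 1 gene of 11 on that list to rise in each comparison, while 1, 1, 2 and 0 fell. The list's mean (0.18, 0.07, 0.12 and 0.08) was positive where camera's direction was down. Endothelial genes rose in 2, 1, 4 and 1 of 11 cases and fell in 3, 1, 1 and 2. Of 5 B cell genes limma called 0, 0, 1 and 0, all lower (0, 0, 2 and 0 at an unadjusted p under 0.05). Of 6 genes of oligodendrocyte precursors it called 1, 0, 1 and 0, all lower (1, 2, 2 and 0 unadjusted). Of 5 genes of ependyma and choroid plexus it called 0, 0, 1 and 1, also lower (1, 0, 2 and 1 unadjusted, in either direction). Fewer than 5 erythroid genes were measured, so that list was not tested.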
